A study of Danio rerio with 6 samples.

How the data were processed

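RNA sequencing measured transcripts in laser-captured cells of the distal pronephric tubule, a segment of the embryonic kidney, of zebrafish embryos at 48 hours post fertilization. Of the 6 libraries, 3 came from embryos wild type for epcam (control) and 3 from embryos homozygous for the epcam allele hi2151 (epcam mutant). All carried the transgenes Tg(wt1b:GFP) and Tg(cdh17:GFP). Per the labels' protocols, total RNA was isolated after reversal of crosslinks and treated with DNase. Reverse transcription used primers of random sequence along with poly-T primers, the whole cDNA was then amplified, and the libraries carried no strand information. How many embryos or captures each library pools is not given in the sources used here. The p-values therefore measure the spread between these 6 samples, part of which may be technical. Amplified copies are not independent molecules, so intervals and floors cover counting error alone.

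The submitters' processing notes name Trimmomatic 0.36.0, TopHat2 2.1.0, DESeq2 and the build GRCz10, and the counting tool is not given in the sources used here. The deposited count table lists 10022 rows on 25 chromosomes, each with a gene name, an Ensembl identifier, a start and an end, and its file name calls the values filtered raw counts. Of these rows, 9641 had an identifier in the reference name table, 1 had none, 45 shared one with another row and 9 carried a date in place of a gene name. The deposited values are whole numbers, but each library except control 2 has a lowest value above 0, shared by 9.46% to 27.7% of its rows. These lowest values were 11 for control 1, 0 for control 2, 32 for control 3, and 30, 31 and 17 for mutants 1 to 3. Every whole number from the lowest value to 30 above it occurs in each library, and the upper quartile of 5 of the libraries is 45 against 45.75 in control 2. Each library was therefore read as counts plus 1 constant, and the constant was subtracted before every test. No label or header states such a constant, so this step is an inference from the values. It departs from the plan to test the deposited counts as they stood, and tests on the values as deposited were added as alternatives.

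2 properties of the file bear on that reading. After subtraction epcam had counts of 10, 15 and 10 in the controls and 0 in each mutant. The authors' deposited table of p-values holds 379 rows with an FDR between 0.00252 and 0.0498 and no fold change. DESeq2 on the counts without the constant called 304 of those rows and ranked them with a Spearman correlation of 0.962 to the deposited FDR, across genes. DESeq2 on the values as deposited called 40 of them, with a correlation of 0.349.

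Without the constant, total counts per library were 552334, 746232 and 188022 for controls 1 to 3 and 172239, 126861 and 250714 for mutants 1 to 3. A floor of 3 counts equals 6.63, 5.46 and 17.6 CPM (counts scaled to the library total by edgeR) in the controls and 16.1, 19.5 and 8.58 CPM in the mutants. The row filter that the file name mentions was looked for in the counts. Every row reaches at least 15, 19 or 9 counts in controls 1, 2 or 3, or at least 11, 12 or 41 counts in mutants 1, 2 or 3. Genes below these limits in every library are not analysed here, and no gene encoded by the mitochondrial genome is among the rows.

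Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The main test was edgeR's quasi-likelihood test (robust dispersion and robust fit) on counts, with TMM scaling, edgeR's filterByExpr by group and Benjamini-Hochberg adjustment at 0.05. It had group as its only term and all 6 libraries in 1 fit. The filter kept 3869 rows and removed 6153, epcam among them, so epcam was tested in the fit without a filter. CPM values are TMM-scaled over all rows. Where a group had no count, the fold is given as a lower bound against 3 counts in each of its libraries. Where a group had 1 to 3 counts in all, the ratio of pooled counts is given with its 95% exact binomial interval. The standard error of a log2 fold change is the fold change divided by the square root of the test's F value.

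Before the data were examined, 27 gene lists were written for nephron segments, processes and other cell types, and ribosomal protein and mitochondrially encoded genes were added by symbol prefix, for 29 lists in all. A row joined a list by its name in the file or by its zebrafish symbol in the name table. The 24 lists with at least 3 tested members went through camera with a preset correlation of 0.01 between genes, adjusted over the lists, and through camera with an estimated correlation and fry. List levels are the summed counts of all listed members in CPM of the library total, without TMM scaling. A single level was compared between groups with a two-sided exact permutation test, whose smallest p with 3 against 3 libraries is 0.1.

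Genes to be named were fixed by a rule before the data were examined. It takes epcam, then the 12 higher and 12 lower genes with the smallest p among those whose groups do not overlap, clone names left out. Genes of that kind are named as not past the threshold where none pass. The rule adds up to 4 members per list by p, the 5 higher and 5 lower genes with the smallest FDR in the authors' deposited table, and the 2 members with the highest mean CPM of each list for another cell type. The result for 1 of the 12 lower genes is not reported here.

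5 choices were made or changed after values had been seen. The first matching of lists took any symbol of the name table in any letter case, which put orthologue names such as that of dldh, a metabolic enzyme, among the Notch genes. It also left 9 rows of S6 kinases, 4 of them tested, in the ribosomal protein list, as the planned prefix takes them. With that first matching 8 lists passed, the same 8 as now, and the ribosomal protein list had a camera adjusted p of 2.54e-09 with 64 tested members. DESeq2 was first run with its independent filtering set for 0.05, which called 407 rows, and then with its default settings as planned, which called 349. For 2 tests of the sequencing project, the bound of 50% written before the test was first applied to the share alone, and both shares, 50.3% and 54.5%, lay just over it. A rule that the 95% interval must exclude 50% was then added, which changed the reading of both from fitting the project to open. The subtraction of the constant is the fourth. Last, the criteria for arguing against an explanation were made stricter: intervals use the effective number of genes, from limma's estimate of their correlation, a fold among controls must hold without each control, and the medians of tubule list members count beside their sums. Thinning was taken to decide nothing where the controls are the deeper group. These criteria left open 4 explanations that the earlier ones had argued against.

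Library names in the labels place controls 1 and 2 in 1 sequencing project, NG-8793, and control 3 with all 3 mutants in another, NG-8710. A fit with the project as a second term and a fit of control 3 against the mutants were 2 fits chosen beforehand. Others were the replicate number as a block, other scalings, other filters, DESeq2, limma-voom with quality weights, edgeR's older fit, other thresholds and each library left out in turn. Alternatives added after seeing the data were the values as deposited, further DESeq2 settings, edgeR's older fit without a filter, removal of each library's trend with gene span, and leaving out the library with the fewest pan-pronephric marker counts in each group.

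The scripts were tested on simulated counts with the means and sizes of these libraries, in which 200 genes changed. At a low spread between replicates, edgeR called 97 of 98 tested genes with a true fold of 4 and 100 of 100 with a true fold of 16. With the common dispersion of these libraries (1.22) given to every gene, it called 0 of 83 and 0 of 78. DESeq2 called 3 of 100 and 41 of 100, together with 18 unchanged genes. No genome sequence was used. Coordinates are those of the deposited table, with the build as the submitters' processing notes name it, and whether counts cover whole gene spans or exons is not given in the sources used here.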

Results

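Gene counts were compared between 3 control and 3 epcam mutant libraries of laser-captured distal pronephric tubule from zebrafish embryos at 48 hours post fertilization. Total counts ranged from 188022 to 746232 in the controls and from 126861 to 250714 in the mutants. Of 10022 listed rows, 7247, 7477 and 7459 were detected in controls 1 to 3 and 7879, 7771 and 9074 in mutants 1 to 3. The 20 most abundant rows of a library held 18.9%, 22% and 21.5% of counts in the controls and 14.5%, 9.65% and 9.83% in the mutants. The correlation of log2 CPM, across genes that are not independent replicates, was 0.441 between controls 1 and 2. It was 0.231 and 0.267 between each of these and control 3, 0.187 to 0.377 among mutants, and 0.109 to 0.283 between groups. Controls 1 and 2 came from 1 sequencing project, and control 3 with all 3 mutants from another. Counts on 7 short rows named otud4 made up between 0.536% and 8.05% of a library and are uncertain, since such copies share reads. The libraries carry no strand information, so reads of overlapping genes on opposite strands cannot be told apart.

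The first comparison asks whether the targeted gene differed. Transcripts of epcam, which encodes an epithelial cell adhesion protein (ENSDARG00000040534, GRCz10 chromosome 13, 8508749 to 8511340), were counted 10, 15 and 10 times in the controls and 0 times in each mutant. The controls had 36.1 ± 19.9 CPM (SD, n = 3), and the mutants were at least 2.45-fold lower (1.68-fold without control 3), against a floor of 3 counts per library. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. In the fit without a filter, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave epcam an adjusted p of 0.206. The same test on the values as deposited gave 0.898, so the difference depends on the subtracted constant. The epcam counts also bore on the choice to subtract it, and are not independent of that choice. The authors' deposited table does not list epcam.

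The second comparison asks which transcripts differed in the tubule of mutants. The lower genes named first are among the 12 with the smallest p, and their direction was fixed by this choice. The apolipoprotein genes apoa2, apoeb and apoa1b had log2 fold changes of -7.67 ± 1.63, -6.74 ± 1.37 and -7.11 ± 1.56 (SE, n = 3 per group). The level of apoeb was 3750 ± 4777 CPM (SD, n = 3) in controls and 35.2 ± 3.48 CPM in mutants. No count of apoa4b.1 was found in the mutants, at least 41.8-fold below controls, and apoa1a had a pooled ratio of 193 (95% interval 53.1 to 1595). The retinol carrier rbp4 had a pooled ratio of 567 (194 to 2751), the iron carrier tfa 147 (40.4 to 1213), and the plasma protein fetub a log2 fold change of -7.23 ± 1.60. The fibrinogen chain fga was at -5.42 ± 1.24. The sarcosine dehydrogenase sardh had a pooled ratio of 57.3 (19.4 to 279.4), and the lysosomal phospholipase pla2g15 was at least 30.9-fold lower. CPM of each of these genes except sardh was highest in control 3 by a wide margin, with an rbp4 count of 2746 against 57 and 87 in controls 1 and 2. Without control 3 the pooled ratio was 33.0 (11.1 to 162.1) for rbp4, 66.4 (18.1 to 552.4) for apoa1a and 60.9 (16.6 to 506.9) for tfa. Log2 fold changes without it were -5.85 ± 1.39 for apoa2, -4.80 ± 1.03 for apoeb, -4.87 ± 1.14 for apoa1b, -5.52 ± 1.36 for fetub and -4.44 ± 1.14 for fga, and the bounds were at least 16.8-fold for apoa4b.1 and 11.5-fold for pla2g15. By the rule that picked them, all 3 controls lay above all 3 mutants for each gene.

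The 12 genes with the smallest p among those higher in the mutants had few or no counts in the controls, and their direction was fixed by this choice. MSANTD2, which encodes a protein with a Myb/SANT-like domain, had 0, 1 and 0 counts in the controls and 48, 88 and 68 in the mutants, a pooled ratio of 347 (95% interval 61.5 to 13760). The cation channel trpm1a had a log2 fold change of 6.24 ± 1.26 (SE, n = 3 per group), and slitrk4, a neuronal membrane protein, 5.26 ± 1.18. No control counts were found for TRHDE (2 of 2), which encodes a peptidase, for the actin-bundling protein espn or for PDGFD, a growth factor. Mutants were at least 24.7-fold, 17.0-fold and 13.4-fold higher for these genes. The dopamine receptor drd4a, the adenylyl cyclase adcy6a and asphd2 were at least 10.4-fold, 10.9-fold and 10-fold higher. The kinase dclk1a had a pooled ratio of 250 (44.1 to 9933), the calcium channel cacna1i 195 (34.4 to 7785) and the receptor gpr22 45.9 (12 to 388.5). With any 1 library left out, the bounds stayed at 7.85-fold (PDGFD, without mutant 1) or more and the pooled ratios at 39.2 (gpr22, without control 3) or more.

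None of the genes named so far passed the threshold in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Those of the second comparison each had an adjusted p of 0.103 in that test, which called 0 of 3869 genes. DESeq2 called all 12 of the higher genes, and apoa2, apoa4b.1, sardh, pla2g15, fetub, apoa1b and fga among the lower ones. It gave no p for apoa1a, apoeb, rbp4 and tfa. At an unadjusted p under 0.05 edgeR counted 521 genes, 329 higher and 192 lower, against 193.45 that chance gives on average, and 63.1% of them were higher against 73.2% with upper-quartile scaling. DESeq2 called 349 genes, 293 higher and 56 lower, but 8 higher and 48 lower with the project as a term and 20 higher and 144 lower on the values as deposited. Limma-voom called 15, 4 higher and 11 lower. Of the 293 genes higher by DESeq2, 158 had 0 counts in the controls and 246 had at most 3. The groups did not overlap for 22.2% of genes, against 10% by chance, with mutants above for 496 genes and below for 364. With the sequencing project as a second term edgeR called 9 genes, all lower, among them apoa1a, apoa2, apoeb, rbp4 and tfa. Within the project of control 3 it called 0 genes, and 1015 of 8035 had an unadjusted p under 0.05. In that comparison, and for genotype in the fit with the project as a term, control 3 is the only control set against the mutants. Within its project the mutants alone give the spread, and control 3 is assumed to vary like them.

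Among the gene lists fixed beforehand, 8 of the 24 tested passed camera, 6 falling and 2 rising, 0 passed with an estimated correlation and 0 by fry. Values of single members depended on single libraries: of 99 members picked from lists by p, 66 were weaker by over 1.5 times without 1 library and 11 turned sign. In the gut, liver and yolk list 20 of 22 tested members were lower, and 14 members passed when adjusted over the list alone, 13 lower and 1 higher. Adjustment over 1 list alone takes no account of the other lists, and 0 of the 22 passed when adjusted over all genes. The list fell as a whole (camera adjusted p = 2.0e-12, adjusted p = 0.36 with an estimated correlation), with a median log2 fold change of -5.31. Its most abundant members were apobb.1, at 16360 ± 17490 CPM (SD, n = 3) in controls and 153.6 ± 136.3 in mutants, and apoa1b. The level of apobb.1 was 4656, 7967 and 36470 CPM in controls 1 to 3, and its log2 fold change was -6.71, or -5.34 without control 3. List members made up 10280, 13550 and 112200 counts CPM of library total in controls 1 to 3 and 2450, 1624 and 1583 in mutants 1 to 3. Of its listed members vil1 is in another list. Without control 3 the list's camera adjusted p was 4.48e-06 with the preset correlation. The estimated correlation between its genes was 0.609, far above the preset one, so camera's small p-values overstate the evidence. With the sequencing project as a term, and within the project of control 3, genotype rests on that library as the only control. Control 3 also had the highest list sum, so those fits add no separate support.

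Ribosomal protein genes fell together, with 57 of 60 tested members lower (camera adjusted p = 1.57e-09, adjusted p = 0.36 with an estimated correlation). The median log2 fold change was -1.46, and rps9, rpl24 and rps3a were at -3.04 ± 1.09, -3.13 ± 1.15 and -2.52 ± 0.95. With the project as a term the list's adjusted p was 3e-05, and within the project of control 3 it was 0.000366, where rpl24 was at 0.02. A mean count of at least 100 ended the call (0.135). Genes of the actin cytoskeleton and myosin II fell, with 21 of 29 tested members lower (camera adjusted p = 0.00727, adjusted p = 0.36 with an estimated correlation). The cytoplasmic actin actb1 was at -2.88 ± 0.96, the formin diaph2 at -3.18 ± 1.06, the filamin flna at -3.08 ± 1.11 (-1.74 without control 3) and the myosin light chain myl12.1 at -3.40 ± 1.33. The project term (adjusted p = 0.110) and a mean count of at least 100 (0.181) ended this call, while within the project of control 3 it was 0.00136. Stress and immediate early genes fell, with 22 of 26 tested members lower (camera adjusted p = 0.00727, adjusted p = 0.436 with an estimated correlation). The mitochondrial chaperone hspa9 was at -3.76 ± 1.22 and the transcription factors klf6a and junbb at -2.45 ± 0.98 and -4.00 ± 1.65 (junbb -2.38 without control 1), while egr3 was at 5.23 ± 2.06. This call ended with the project as a term (0.756) and within the project of control 3 (0.735), where junbb was at 1.11, and with a mean count of at least 100 (0.135) or a count in all libraries (0.133). Ionocyte and V-ATPase genes fell, with 7 of 7 tested members lower (camera adjusted p = 0.0101, adjusted p = 0.36 with an estimated correlation). The carbonic anhydrase ca2 was at -2.94 ± 1.02, the proton pump subunit atp6v0ca at -2.40 ± 1.21 and the sodium pump subunit atp1a1a.2 at -2.17 ± 1.05. The project term (0.0912) and a count in all libraries (0.133) ended that call, and within the project of control 3 it was 0.0260.

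Keratinocyte and periderm genes fell, with 9 of 9 tested members lower (camera adjusted p = 0.0323, adjusted p = 0.488 with an estimated correlation). The skin keratin krt4 had counts of 97, 179 and 4263 in the controls and 7, 2 and 17 in the mutants. Its log2 fold change was -8.06 ± 1.99 (-2.98 without control 3). It was the 1 member that passed adjusted over the list alone, but it did not pass over all genes (edgeR adjusted p = 0.1135). The member next by mean CPM, krt8, was at -1.09 ± 1.01, and its groups overlapped. The list's counts were 2982, 3942 and 44900 CPM of library total in the controls and 3780, 1395 and 1544 in the mutants, and 10 of its 29 listed members are in other lists. This call ended without control 3 (0.278), while the values of 3.69e-05 with the project as a term and 1.04e-16 within the project of control 3 rest on that library. It also ended without control 3 and mutant 2, the libraries of each group with the fewest pan-pronephric counts (0.738), and with the trend over gene span removed (0.0589). Limma-voom (0.0879), the values as deposited (0.131), a mean count of at least 100 (0.135) and a count in all libraries (0.133) ended it too. Genes of cilia and multiciliated cells rose, with 11 of 16 tested members higher (camera adjusted p = 0.0323, adjusted p = 0.436 with an estimated correlation). The axonemal dynein dnah9 was at 3.73 ± 1.09, cfap57 at 5.01 ± 1.66 (2.38 without mutant 1) and the transport protein ift140 at 3.46 ± 1.42. Their summed level was 2212, 2724 and 723.3 CPM of library total in the controls and 6677, 3728 and 4216 in the mutants (exact permutation p = 0.1). This call ended without control 3 (0.278), without mutant 3 (0.0536), without control 3 and mutant 2 (0.345), with the span trend removed (0.0864), on the values as deposited (0.184), with limma-voom (0.0947) and with a count in all libraries (0.111). Its adjusted p was 0.0107 with the project as a term and 0.0024 within the project of control 3. Neuron and glia genes rose, with 5 of 5 tested members higher (camera adjusted p = 0.00123, adjusted p = 0.36 with an estimated correlation). The transcription factor zic2a and the splicing factor nova1 had no control counts and were at least 8.14-fold and 6.62-fold higher. Both passed adjusted over the list alone but not over all genes (edgeR adjusted p = 0.106 and 0.111). The list's median log2 fold change was 3.42, or 2.73 with these 2 genes at their bound. The project term ended this call (0.159), as did the comparison within the project of control 3 (0.391).

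Nephron lists did not pass. Of 13 distal tubule genes 5 were higher and 8 lower (camera adjusted p = 0.829), with a median log2 fold change of -0.28, a mean of 0.29 and an upward test. The thick-limb transporter SLC12A1 was at 4.65 ± 1.47 and the transcription factor tfap2b at 3.16 ± 1.13 (2.05 without mutant 1), while the distal transporter slc12a3 was at -1.56 ± 1.26. Pan-pronephric epithelial genes were lower in 8 of 9 members (0.266), with the transcription factor hnf1ba at -1.72 ± 1.03 and the Notch ligand jag2b at 3.74 ± 1.27 (2.22 without mutant 1). The pan-pronephric sum was 12770, 11010 and 1351 CPM of library total in the controls and 11610, 2483 and 4910 in the mutants (exact permutation p = 0.9). The distal sum was 3961, 3902 and 1441 against 5179, 1033 and 2844 (exact permutation p = 0.7). Of 4 proximal tubule genes 3 were higher (0.126). The endocytic receptor lrp2b, at 4.94 ± 1.64 (3.40 without mutant 1), passed adjusted over the list alone but not over all genes (edgeR adjusted p = 0.205). The 4 podocyte and glomerulus genes had an adjusted p of 0.829, with foxc1a at 3.83 ± 1.60.

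Junction and signalling lists did not pass either. Of 30 epithelial junction genes 10 were higher and 20 lower (camera adjusted p = 0.302). The claudin cldn10b had a pooled ratio of 190 (95% interval 33.5 to 7584, and 101 without control 2). It passed adjusted over the list alone but not over all genes (edgeR adjusted p = 0.106). Planar cell polarity genes were higher in 12 and lower in 14 members (0.792), with a mean of 0.02 and a downward test. In the canonical Wnt list 13 were higher and 14 lower (0.829), with a median of -0.19 and an upward test. The ligand wnt2bb was at 6.67 ± 1.77 (5.62 without mutant 2), the receptor fzd10 at 3.94 ± 1.29 and the kinase csnk1a1 at -2.84 ± 1.01. In the Notch list 7 were higher and 8 lower (0.934), with a mean of 0.37. The receptor notch3 was at 3.72 ± 1.49 but at 0.31 without mutant 3, and the glycosyltransferase lfng had a pooled ratio of 42.5 (11.2 to 360.4, and 26.1 without control 1). TGF-beta and BMP genes were higher in 5 and lower in 10 members (0.792), with a mean of 0.03 and a downward test. Extracellular matrix and integrin genes were higher in 15 and lower in 30 members (0.0575), with the integrin itgb5 at 3.45 ± 1.05 and the collagen col1a1a at -3.11 ± 1.05. Mesenchymal transition genes were higher in 4 of 7 members (0.277), with zeb1b at 2.72 ± 1.13. Cell cycle genes were higher in 11 and lower in 16 members (0.675), with the spindle protein tpx2 at 2.48 ± 1.01. Apoptosis and p53 genes were lower in 8 of 11 members (0.331), with ccng1 at -2.80 ± 1.16.

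Markers of other cell types varied between libraries. Skeletal muscle genes were higher in 7 and lower in 14 of 21 members (camera adjusted p = 0.559), with a median of -0.51 and an upward test. Their sum was 34400 CPM of library total in control 1, 1627 and 1298 in controls 2 and 3, and 5893, 9869 and 15890 in the mutants. The slow myosin smyhc1 had no control counts and was at least 49.8-fold higher (7.74-fold without mutant 2). It passed adjusted over the list alone but not over all genes (edgeR adjusted p = 0.103), and its close copies make it uncertain. Endothelial genes were higher in 4 of 5 members (0.829). The receptors aplnra, at 5.02 ± 1.66, and flt4, at -3.31 ± 1.09, passed adjusted over the list alone but not over all genes (edgeR adjusted p = 0.201 and 0.202). Of 5 immune and inflammatory genes (0.555, median 0.10 and a downward test), the complement gene c3a.1 was at -3.86 ± 1.16. It passed adjusted over the list alone but not over all genes (edgeR adjusted p = 0.178). Lists for corpuscles of Stannius, red blood cells, notochord and cartilage, and pigment cells had 1, 1, 2 and 2 tested members, too few for the test. Their members stc1l, sptb, ctgfa and tyrp1b were at 0.59 ± 1.37, -0.07 ± 1.21, -1.06 ± 1.2 and -1.25 ± 1.05, and stc1l was at -0.97 without mutant 2. No mitochondrially encoded row was present.

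**Figure D1:**
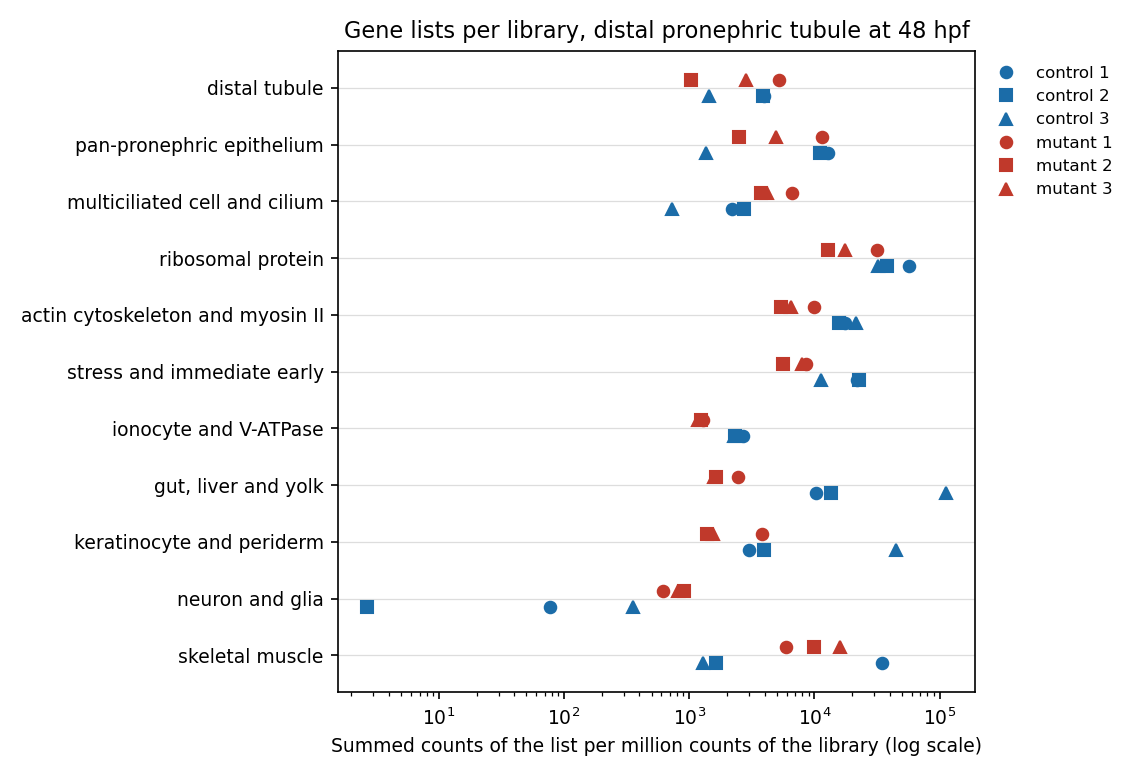
Summed counts of 11 gene lists in CPM of the library total, on a logarithmic axis, with controls in blue, mutants in red and shapes marking the replicate number. The gut, liver and yolk sum lies at 10280 or above in each control and at 2450 or below in each mutant.

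**Figure D2:**
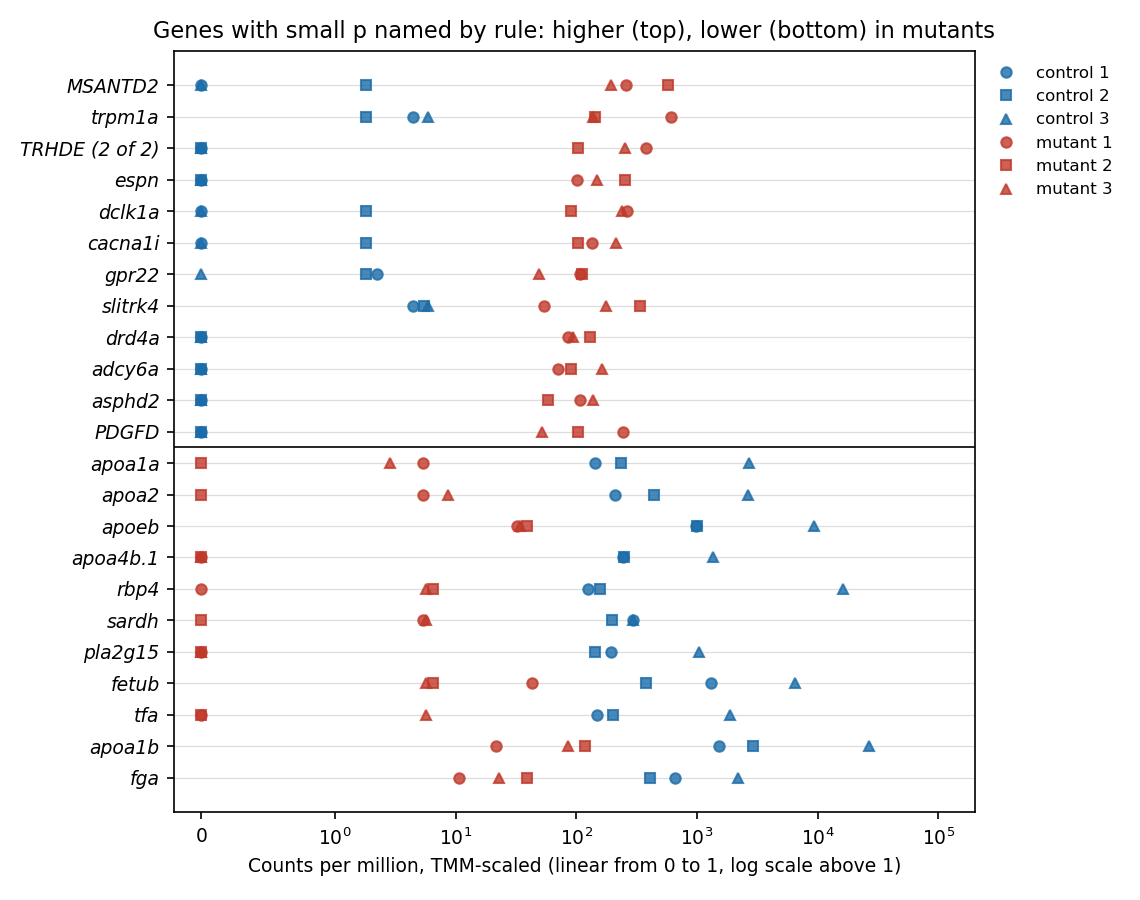
TMM-scaled CPM in each library for the higher and lower genes named by rule, on an axis that is linear from 0 to 1 and logarithmic above. For each gene all 3 libraries of 1 group lie on 1 side of the other group.

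The third comparison set the sequencing projects against each other, with genotype held as a term. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes and counted 622 at an unadjusted p under 0.05, and DESeq2 called 111, of which 16 were higher and 95 lower in the project of controls 1 and 2. This contrast rests on the controls alone, since the mutants came from 1 project. It sets controls 1 and 2 against control 3, so the project cannot be told apart from that 1 library. Control 3 also had the highest gut, liver and yolk sum and the lowest pan-pronephric sum of the controls.

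The authors' deposited table lists 379 rows, 329 higher and 50 lower in mutants by mean CPM. Its smallest FDR among higher genes belonged to MSANTD2 (0.00252), fam60al (0.00574), TRHDE (2 of 2) (0.00699), and tns2b and wnt2bb (0.0114 each). Counts of fam60al were 0 in the controls and 1, 167 and 54 in the mutants, and those of tns2b were 0 and then 5, 89 and 24. Among lower genes they were apobb.1, fetub and apoa2 (0.00252 each), pla2g15 (0.00955) and fga (0.0158). Of the 329 higher rows, 195 had 0 counts in the controls and 284 had at most 3, and of the 50 lower rows 22 had at most 3 in the mutants. DESeq2 called 304 of the 379. edgeR's filter kept 128, all with an unadjusted p under 0.05 in the direction of their mean CPM, of which 0 passed its adjusted threshold. The authors' rows were picked from these same libraries, so these overlaps are no independent support for the rows.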

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

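The count of 0 genes by edgeR's quasi-likelihood test held with each library left out (0 to 0), within the project of control 3, with other scalings and filters and at other thresholds. It became 9 with the project as a term, 349 with DESeq2, 15 with limma-voom, and, in alternatives chosen after seeing the data, 164 with DESeq2 on the deposited values, 214 with DESeq2 on edgeR's rows, 407 with DESeq2 filtering set for 0.05, 53 with edgeR's older fit without a filter and 56 with DESeq2 and the project as a term. The 8 lists became 5 with the project as a term, 2 at a mean count of at least 100, 3 with a count in all libraries, 0 with an estimated correlation and 0 by fry, and 7 to 11 with a library left out. The list membership as first matched, added after seeing the data, kept 8. Overlap with the authors' table moved from 0 to 304 with DESeq2, 1 with the project as a term and 40 with DESeq2 on deposited values. The contrast of projects moved from 0 to 111 with DESeq2. The adjusted p of epcam was 0.18 to 0.401 with a library left out and 0.206 to 0.898 otherwise. Of 72 named genes in 25 settings, 1468 values kept direction and side of the threshold, 161 passed it and 4 reversed: junbb to 1.04 with the project as a term, 1.11 within the project of control 3 and 1.01 with DESeq2 and the project as a term, and rpl24 to 0.02 within that project. The cause was not tested. With the replicate number as a block 0 genes and 8 lists passed and the adjusted p of epcam was 0.596, with 395 genes at an unadjusted p under 0.05 against 521. Libraries with the same number deviated with correlations of 0.0802, -0.0569 and 0.0283 across genes, within the range of -0.124 to 0.108 for different numbers. These values show no pairing by number and cannot exclude one. The median log2 fold change of all genes was -0.10 with TMM, 0.09 with RLE, 0.19 with upper-quartile scaling and 0.60 with none. edgeR's older fit was not run for lists, since camera does not use it. DESeq2 gives epcam no adjusted p, and filters remove it. With the common dispersion of these libraries given to every gene, edgeR recovered 0 of 78 simulated 16-fold changes. Its count of 0 therefore does not show that few genes differed. That simulation does not give the power for genes of lower dispersion.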

Other observations

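Some markers of other cell types, picked by mean CPM, were removed by the main filter and differed between single libraries. The melanin enzyme dct had counts of 1, 249 and 32 in the controls and 0, 0 and 2 in the mutants, a pooled ratio of 83.0 (95% interval 22.8 to 688.5), with 249 of them in control 2, and dct had an adjusted p of 0.166 in edgeR with no filter and 0.0511 in DESeq2. The endothelial cadherin cdh5 had 161, 16 and 6 in the controls and 1, 49 and 1 in the mutants, with adjusted p values of 0.913 and 0.988. CASR, of the corpuscles of Stannius list, had 0, 15 and 9 in the controls and 0, 3 and 59 in the mutants. Counts of tfr1a, of the red blood cell list, were 102, 6 and 0 in the controls and 1, 11 and 7 in the mutants.

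The splits for edgeR's calls and the tests on gene span, on tubule expression in proportion, on the span trend and on fewer tubule cells were chosen only after the result was seen. The criteria that intervals allow for correlated genes and that no single library decides were also chosen after the values were seen.

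With 10 splits of the 6 libraries a share under 0.05 is out of reach. edgeR called 0 genes in the real split and at most 0 in the others, so that all 10 splits gave as many. At an unadjusted p under 0.05 the real split gave 521 genes and the highest other 371, and DESeq2 called 349 against 75. Camera passed 8 lists against 4, and for each of these 3 counts 1 split, the real one, gave as many. The 371 and 75 came from controls 1 and 2 with mutant 1, set against control 3 with mutants 2 and 3. Controls 1 and 2 with mutant 2 gave 183 genes and 34 DESeq2 calls, and with mutant 3 they gave 212 and 10. Splits that parted controls 1 and 2 gave 118 to 173 genes and 1 to 13 calls.

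Rows detected in all mutants and no control numbered 227, against 59 the other way. The test of lower depth in the controls decides nothing, since they were the deeper group (median total 552334 against 172239) and thinning could only raise the excess, which became 8.34 to 1. Background reads in proportion to gene span stay open: at an unadjusted p under 0.05 the higher genes had a median span at percentile 78.3 of matched random sets and the lower genes at percentile 0 (15701 bp), and the count-weighted geometric mean span was 18926 to 27415 bp in the mutants against 14896 to 16558 bp in the controls. The sequencing project stays open too: control 3 lay nearer the mutants for 50.3% of 1172 higher genes (interval 13.0 to 87.3, for 6.47 effective genes) and 63.2% of all lower genes. These shares were 29.1% and 51.9% for control 1 and 31% and 39.6% for control 2 when each was left out. Mutants 1, 2 and 3, when left out, lay nearer the controls for 44.0%, 36.7% and 24.4% of higher genes. For lower genes their shares were 37.1%, 21.55% and 45.0%. Differences among the mutants cannot reflect the project, which they share, and control 3 had the highest share in both directions. A response to loss of epcam may also account for the excess, as an untested hypothesis.

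Liver, gut and yolk genes were lower in the mutants by camera (adjusted p = 2.0e-12), but the list did not pass with an estimated correlation (0.36) or by fry (0.157). Control 3, which shares the mutants' sequencing project, lay nearer the mutants for 0% of 13 genes, which goes against the project as the cause. The project still stays open, since this reads 1 library and allows up to 92.4% for 1.43 effective genes. With the project as a term the list's adjusted p was 1.35e-24, in a fit where genotype likewise rests on control 3. The test of expression by tubule cells in proportion to their markers decided nothing. The ratio of the list to the pan-pronephric list differed 103-fold among the controls but 1.53-fold without control 3. This ratio was 0.805, 1.23 and 83 in controls 1 to 3 and 0.211, 0.654 and 0.322 in mutants 1 to 3. Every mutant lay below every control. The list was taken up because it was lower in the mutants, so this order is no separate evidence against a proportion shared by both groups. Mutant 2 lay near control 1, and 3 against 3 libraries cannot settle it. Tissue of another organ carried into the control captures may be a source and stays open: the controls' profiles of the list correlated at 0.830, 0.737 and 0.621, with a lowest percentile of 91.8 among matched sets, short of the 95 written beforehand, and an effect of genotype stays open, untested.

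4 lists, ribosomal protein, actin, stress, and ionocyte and V-ATPase, passed camera as lower in the mutants. They did not pass with an estimated correlation (adjusted p = 0.36, 0.36, 0.436 and 0.36), and the project as a term ended the calls of the last 3 (0.110, 0.756 and 0.0912). A trend with gene span is argued against only as the whole cause of these camera passes, since 4 of 4 lists passed again after its removal. That repeat used the preset correlation alone, and no test with an estimated correlation or by fry followed the removal. Fewer tubule cells in the mutant captures may contribute and stay open: the sums of the tubule lists overlapped between groups with a median log2 ratio of -0.221, against -1.18 for the 4 lists, while members of the pan-pronephric and distal lists had median log2 fold changes of -1.35 and -0.28, against -1.46, -1.14, -1.17 and -1.87 for the 4 lists in the order above. The sequencing project stays open, with control 3 nearer the mutants for 54.5% of 33 genes (interval 3.68 to 98.1), against 18.8% and 23.8% for controls 1 and 2. Mutants 1, 2 and 3, when left out, lay nearer the controls for 55.6%, 27.3% and 81.8%. Differences among the mutants cannot reflect the project, which they share. The share of 54.5% pools 4 lists whose sums differed among the controls. In controls 1 to 3 the stress sum was 21750, 22650 and 11220 CPM of library total. Ribosomal protein sums were 56990, 37770 and 32180, actin sums 17710, 15630 and 21680, and ionocyte and V-ATPase sums 2669, 2312 and 2298. For genotype, the fit with the project as a term rests on control 3 as the only control. Genotype stays open as an untested hypothesis.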
